A study of Mus musculus with 4 samples.

How the data were processed

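Samples of Sirp-a+ dendritic cells from the spleens of IRF4 KO and WT mice, 2 per genotype, were each hybridised to 1 array. Per the labels' protocols, spleens were digested with collagenase B and DNase, and RNA of the sorted cells was amplified and biotin-labelled with a whole-transcript kit, so each array has 1 colour. The deposited intensity values are probeset summaries on a linear scale, made with RMA per the submitters' processing notes. The version of RMA, its software, its normalization and any filter on probesets are not given in the sources used here. The quantiles of the 4 deposited columns differ: over all probesets the upper quartile was 136 and 131 for IRF4 KO and 127 and 122 for WT, and the interquartile range was 2.77 and 2.66 against 2.56 and 2.44 on the log2 scale. RMA can compress dim probesets, so differences of dim genes may be understated.

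The intensities were transformed to log2 with no pseudocount. Of 30177 probesets, the platform annotation gave exactly 1 gene symbol for 21789 and several for 1621, and did not list 6767, which are unnamed here. The entrez ID of 21698 named probesets was found in a gene table of GRCm38.p6, and no symbol changed through it. The genome build of the probesets is not given in the sources used here, so that table served only for names and for the order of genes along chromosomes. Each of 19938 genes was represented by its brightest probeset over all arrays, and 12364 genes above the 40th percentile of all probesets' means (intensity 34.6) were tested, since the table holds no detection calls.

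Genotypes were compared with limma 3.58.1 (lmFit and eBayes, no block) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The fit had 7.25 degrees of freedom, of which 5.25 came from the prior, and the median residual SD was 0.104 on the log2 scale. With 2 arrays per group, the number of arrays limits the precision. The design, the settings tried and 30 gene lists were fixed before the data were examined. Sets of at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over 29 lists; the list of Xist and Y-linked genes was kept out. Camera with the preset correlation passed 7 higher and 2 lower lists. With an estimated correlation none passed, 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.353. Fry, which does not compare a list with other genes, passed 3 lists in one direction and 26 in either direction. The 3 were the macrophage, mitosis and S-phase lists. The other lists past camera did not pass fry in one direction. The lists share some members, such as Ccl5, Irf7, Irf8 and Cd209a.

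Genes were named by a rule: Irf4, the 12 genes with the largest differences in each direction whose arrays did not overlap, and up to 4 members of each list with the largest differences at an unadjusted p under 0.05; predicted genes and those with clone names were left out. Members of the lists named beyond it (Ifit1, Ifit3, Klf4, Zbtb46, Il1a, Cxcl10, Ccr7, Aim2, Adgre1, Xcr1, Siglech, H2-Aa, H2-Ab1, H2-Eb1, Cd74, Fos, Fosb, Jun and Junb) were chosen after their values were seen. Leaving out an array leaves 1 array in its group, which is then assumed to vary like the other group. Alternatives were quantile normalization on top of the deposited values, subtraction of each array's median, no brightness filter, a stricter filter at the 60th percentile, the mean of a gene's probesets, a trended and robust variance, the replicate number as a block, other thresholds and each array left out.

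The test was tried on simulated data of 12364 genes with 200 changed between IRF4 KO and WT. It recovered 17.9% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 98.5% of those changed by 2, with 2 false calls among 141. With no gene changed it made no calls, and 4.76% of genes had an unadjusted p under 0.05. The simulated values were normal and independent between genes, with variances drawn from the prior that limma fitted to these arrays. The simulated arrays had no differences in distribution such as those of the deposited columns. These rates therefore describe the test under its own assumptions, and the share of false calls on the real arrays was not measured.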

Results

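Gene expression was measured on microarrays in Sirp-a+ dendritic cells sorted from mouse spleen. Sirp-a, also called CD172a, is a signal-regulatory receptor that marks type 2 conventional dendritic cells (cDC2), a class of antigen-presenting cells. The sorted cells were B220-negative, MHC class II-positive, CD11c-positive, CD24-negative and Sirp-a-positive, and came from unstimulated female C57Bl/6 mice that were wild type (WT) or lacked IRF4 (IRF4 KO), a transcription factor of the interferon regulatory factor family. Each genotype had 2 arrays. Nothing in the labels says that the arrays of a genotype came from separate mice, so p-values measure only the spread between these arrays, which may be technical. Of 30177 probesets, 12364 genes with 1 named probeset each passed the brightness filter. The median intensity over all probesets was 45.4 and 46.4 on the IRF4 KO arrays and 46.6 and 48.7 on the WT arrays, and the number of arrays limits the precision of every value. Xist, the noncoding RNA of the inactive X chromosome, had an intensity between 1478 and 1537 on all 4 arrays, and the Y-linked genes Kdm5d, Eif2s3y and Uty stayed between 4.83 and 18.0.

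The deleted gene was examined first, as a check of the labels. The Irf4 probeset had an intensity of 76.0 ± 4.88 (SD, n = 2) in IRF4 KO cells and 748 ± 22.5 (SD, n = 2) in WT cells. It fell by 3.30 ± 0.10 (SE) on the log2 scale, to a level 9.85-fold below that of WT cells (limma, adjusted p = 3.1e-05). Both IRF4 KO arrays lay below both WT arrays. Which part of the transcript the probeset covers is not given in the sources used here.

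The main comparison asked which genes differ between Sirp-a+ dendritic cells without and with IRF4. In IRF4 KO cells 1045 genes were higher and 440 were lower in limma at an adjusted p under 0.05 among 12364 tested. Differences are given on the log2 scale, IRF4 KO against WT, with the SE of the limma fit, and intensities as means of 2 arrays per genotype. Mmp12, a secreted metalloelastase, had the largest difference of any called gene and fell by 4.06 ± 0.10, from 849 to 50.8 (limma, adjusted p = 8.51e-06). Adgrl3, an adhesion G protein-coupled receptor, fell by 2.89 ± 0.12, Rasgrp3, a guanine nucleotide exchange factor for Ras, fell by 2.87 ± 0.14, and Klri1, a killer cell lectin-like receptor, fell by 2.68 ± 0.10. The others among the 12 lowest were H2-M2, Mir680-1, Ppp1r14a, the C-type lectin gene Cd209a, the metalloprotease gene Adam8, the chemokine gene Ccl4, Serpinb6b and Stra6l, with differences from -1.93 to -1.62.

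The 12 genes that rose furthest held several families. Ifi205, an interferon-inducible gene of the PYHIN family, rose by 3.61 ± 0.18 (limma, adjusted p = 0.000203), and its relatives Ifi206 and Ifi203 rose by 1.91 ± 0.30 and 1.81 ± 0.11. The paired immunoglobulin-like receptor genes Pilra, Pilrb1 and Pilrb2 rose by 2.94 ± 0.21, 2.06 ± 0.15 and 1.99 ± 0.11. Ly6i, which encodes a surface protein of the Ly6 family, rose by 2.71 ± 0.12, and the interferon-induced membrane protein gene Ifitm1 rose by 1.95 ± 0.10 (5235 against 1359). Nccrp1, the actin-capping gene Capg, the carbonic anhydrase gene Car2 and Ace, which encodes angiotensin-converting enzyme, rose by 1.79 to 1.90. Members of the Ifi200, Pilrb, Ly6 and Klri families are similar in sequence, so the share of each member in its probeset's signal is uncertain. The dimmer genotype lay below the filter level of 34.6 for Ifi205, Ly6i, Ifi206 and Rasgrp3; with it set at that level the differences were 11.1-fold, 4.31-fold, 2.56-fold and 6.51-fold.

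The number of called genes was 1485 with all 4 arrays and fell with any 1 array left out. A genotype left with 1 array has no spread of its own, so the spread then comes from the other genotype. The IRF4 KO arrays lay closer together than the WT arrays (median absolute log2 difference 0.105 against 0.132). A lower count without an IRF4 KO array therefore does not show that the calls rested on that array. The share of higher genes among the calls was 70.4%, and after quantile normalization of the deposited values it was 58.1% (757 higher and 547 lower). With each array's median subtracted it was 79.7% (1417 higher and 360 lower). Both arrays of a genotype lay beyond both of the other for 59.0% of the tested genes. By chance 33.3% would do so on average. Genes on an array vary together, so the spread around that average is unknown. The share is therefore no measure of an effect of genotype.

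**Figure D1:**
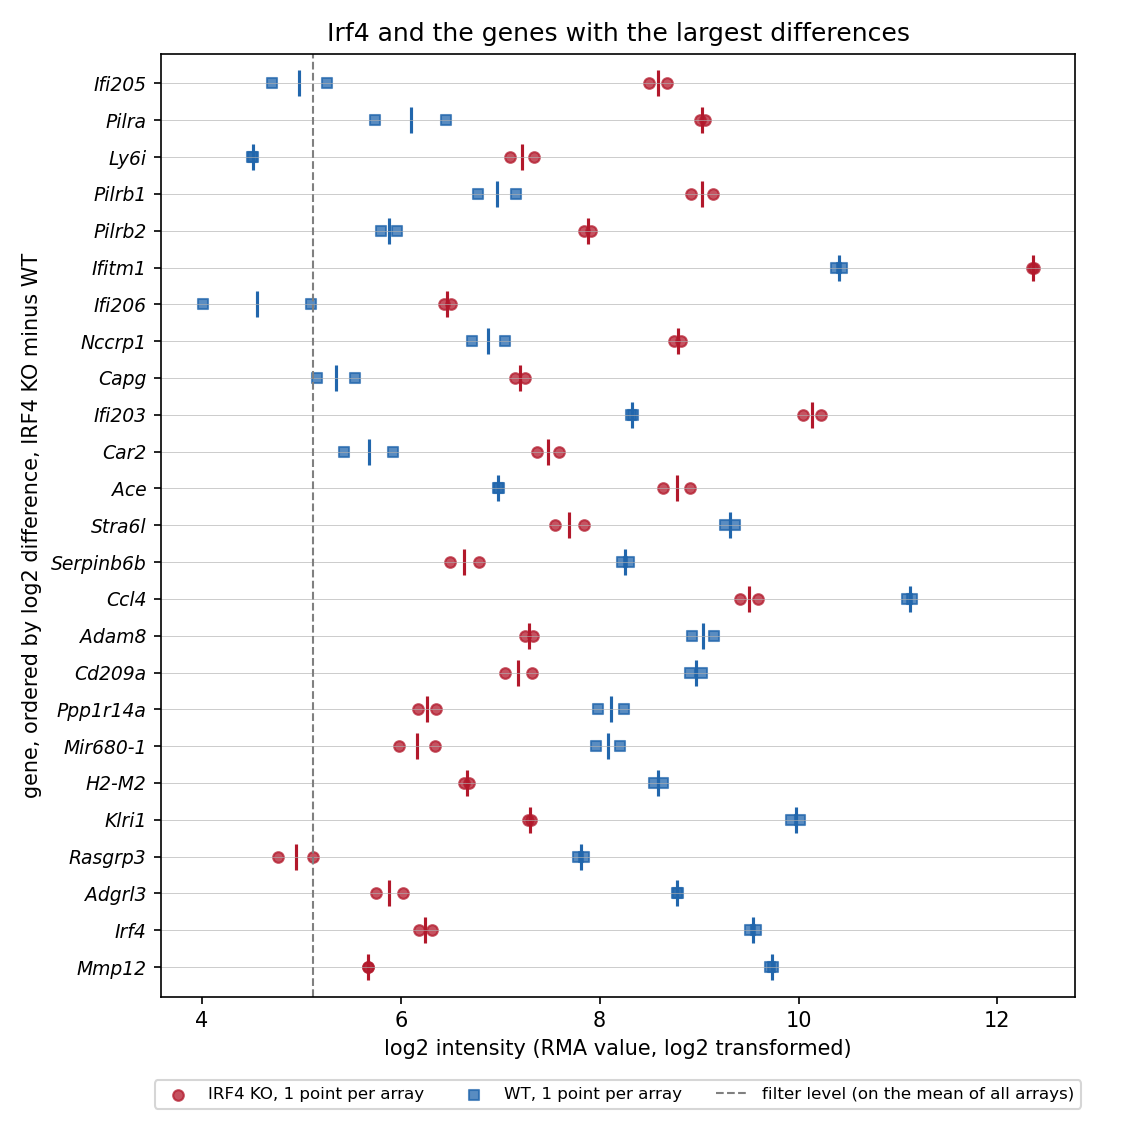
Log2 intensity (horizontal axis) of Irf4 and of the 12 highest and 12 lowest genes (vertical axis), with a red circle for each IRF4 KO array, a blue square for each WT array, a vertical tick at each genotype's mean and a dashed line at the filter level. In every gene drawn, both IRF4 KO arrays lie on the same side of both WT arrays, which the naming rule required of all but Irf4. The differences run from Ifi205 at 3.61 to Mmp12 at -4.06.

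Genes of cell division were higher in IRF4 KO cells. Of 26 tested mitosis genes, 23 rose, none fell and 3 did not pass, with a median difference of 0.88, and 25 rose when adjusted over the list alone. Bub1, a kinase of the spindle checkpoint, rose by 1.24 ± 0.13 (192 against 82.0), Ccna2, which encodes cyclin A2, by 1.15 ± 0.13, and the proliferation marker gene Mki67 by 1.13 ± 0.16 (499.7 against 232). Of 25 S-phase genes, 19 rose, none fell and 6 did not pass, with a median of 0.63, and 23 rose when adjusted over the list alone. Ccne2, which encodes cyclin E2, rose by 1.20 ± 0.17, the ribonucleotide reductase gene Rrm2 by 1.13 ± 0.10 and the replication licensing gene Cdc6 by 1.04 ± 0.14. Both lists were higher as sets (camera with a preset correlation, adjusted p = 1.54e-16 for mitosis and 9.74e-12 for S phase). For each of these lists camera gave adjusted p = 0.353 with an estimated correlation. The counts were lower with fewer arrays: without IRF4 KO replicate 1, 13 mitosis and 7 S-phase genes rose, and without IRF4 KO replicate 2, 9 S-phase genes did.

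Interferon-stimulated genes were higher in IRF4 KO cells, though not all of them. Of 27 tested, 17 rose, none fell and 10 did not pass, with a median difference of 0.63. Adjusted over the list alone, 17 rose and 1 fell. Irf7, a transcription factor of the interferon response, rose by 1.49 ± 0.12 (360.1 against 129), the GTPase gene Irgm1 by 1.29 ± 0.15, and the oligoadenylate synthetase genes Oas2 and Oas3 by 1.25 ± 0.13 and 1.15 ± 0.10. Ifit1 and Ifit3, classical members of the list, had differences of -0.23 ± 0.12 and -0.37 ± 0.10 that did not pass (limma, adjusted p = 0.239 and 0.0522). The list was higher as a set (camera, adjusted p = 6.51e-08), with adjusted p = 0.579 with an estimated correlation and 0.0921 with fry. Only 9 of its genes rose without IRF4 KO replicate 1 and 10 without IRF4 KO replicate 2.

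Transcription factors of dendritic cells were mixed. Of 30 tested, 7 rose, 3 fell and 20 did not pass, and adjusted over the list alone 9 rose and 4 fell. Besides Irf7, Irf8, which type 1 conventional (cDC1) and plasmacytoid dendritic cells need, rose by 1.01 ± 0.11 (221 against 109.7). Irf1 rose by 0.81 ± 0.12 and the repressor gene Bcl6 fell by 0.75 ± 0.11 (395 against 667), and limma gave these an adjusted p of 0.0596 without IRF4 KO replicate 2 and of 0.057 without IRF4 KO replicate 2. Klf4 and Zbtb46, factors of cDC2 and of conventional dendritic cells, were at 0.04 ± 0.11 and -0.13 ± 0.10 and did not pass. The list did not shift as a set (camera, adjusted p = 0.891). Without IRF4 KO replicate 1 or 2, 3 of its genes rose and 1 fell, and without WT replicate 2, 4 rose.

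Genes that distinguish subsets of cDC2 moved in both directions. Of 14 genes of the Notch-dependent subset with high ESAM, 4 fell, 3 rose and 7 did not pass, and adjusted over the list alone 4 fell and 4 rose. The proton-sensing receptor gene Gpr4 fell by 1.13 ± 0.12 and Adam23 by 0.89 ± 0.10 (596 against 1105), while Cd7 rose by 1.09 ± 0.14 (2834 against 1330) and Tbx21, which encodes T-bet, by 0.81 ± 0.10. The set did not shift (camera, adjusted p = 0.902), and its median of 0.08 and mean of -0.01 differed in sign. Of 14 genes of the subset with low ESAM and of monocytes, 6 rose, 1 fell and 7 did not pass, and adjusted over the list alone 8 rose and 2 fell. Ms4a7 rose by 0.90 ± 0.11, and Cd209a was the member that fell, by 1.78 ± 0.13. This list was higher as a set (camera, adjusted p = 0.0398), with adjusted p = 0.757 with an estimated correlation. The camera call was lost without IRF4 KO replicate 1 (adjusted p = 0.145), without WT replicate 2 (0.0511), with each array's median subtracted (0.0557) and with the stricter brightness filter (0.357). Without IRF4 KO replicates 1 and 2, the higher genes numbered 1 and 2 in this list and 2 and 2 in the Notch-dependent list, which had 3 lower genes without replicate 1. Without WT replicate 2, 4 genes of this list and 2 of the Notch-dependent list rose. Macrophage markers, of which 12 of 16 rose (median 0.74, given below), were higher on the same arrays.

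Genes of cytokines and chemokines moved in both directions. Of 28 cytokine and chemokine genes, 8 fell, 6 rose and 14 did not pass, and adjusted over the list alone 9 fell and 6 rose. The chemokine genes Ccl4 and Ccl3 fell by 1.62 ± 0.11 and 1.51 ± 0.11 (Ccl3 1485 against 4220), Ccl5 fell from an intensity of 2674 to 1331, and Tnf fell by 1.43 ± 0.11 (369 against 992). Il1a, which encodes interleukin-1 alpha, rose by 0.94 ± 0.12 and the interferon-inducible chemokine gene Cxcl10 by 0.85 ± 0.10. The list did not pass as a set (camera, adjusted p = 0.109), but was lower with the stricter brightness filter (0.0305) and with a trended, robust variance (0.0453). Without IRF4 KO replicate 1, 4 of its genes fell and 2 rose, without IRF4 KO replicate 2, 4 fell and 3 rose, and the number that rose was 4 without WT replicate 2.

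Some genes of dendritic cell maturation and migration were lower in IRF4 KO cells, though most did not pass. Of 26 tested, 7 fell, none rose and 19 did not pass, with a median difference of -0.25, and adjusted over the list alone 11 fell and 2 rose. Besides Ccl5, Stat4, which transduces the interleukin-12 signal, fell by 0.90 ± 0.10 (456 against 849). Ccr7, the receptor that guides dendritic cells to lymph nodes, fell by 0.52 ± 0.10 (1724 against 2467), with a limma adjusted p of 0.138 without IRF4 KO replicate 1 and 0.109 without IRF4 KO replicate 2 and 0.0529 without WT replicate 1. The list was lower as a set only in camera with its preset correlation of 0.01 (adjusted p = 0.000394). With camera at the estimated correlation of 0.288 the list had adjusted p = 0.757, and with fry 0.143. Of its genes, 2 fell without IRF4 KO replicate 1, 2 without IRF4 KO replicate 2 and 3 without WT replicate 1. On the same arrays macrophage markers were higher (median 0.74) and immediate-early genes, which respond to dissociation, were lower (median -0.19), as given below.

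Immediate-early genes, which respond to stimulation and to tissue dissociation, were lower in IRF4 KO cells, though not all of them. Of 25 tested, 8 fell, 1 rose and 16 did not pass, and adjusted over the list alone 8 fell and 2 rose. Ier3 fell by 0.94 ± 0.12 and the zinc finger transcription factor genes Egr3 and Egr2 by 0.88 ± 0.10 and 0.83 ± 0.10. Fos, Fosb, Jun and Junb, classical members of the list, did not pass (limma, adjusted p = 0.240, 0.951, 0.186 and 0.835). The member that rose was Hspa1a, which encodes an inducible heat-shock chaperone, by 1.52 ± 0.13 (435 against 152). The list was lower as a set (camera, adjusted p = 0.000182), with adjusted p = 0.757 with an estimated correlation and 0.127 with fry. Of its genes, 3 fell without either IRF4 KO replicate. The lower maturation list and the higher macrophage markers were measured on the same arrays.

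Of 19 MHC class II presentation genes, 4 fell, 1 rose and 14 did not pass, and adjusted over the list alone 4 fell and 2 rose. Ctsd, which encodes the lysosomal protease cathepsin D, rose by 1.31 ± 0.11 (905 against 363), and the tetraspanin gene Cd9 fell by 0.84 ± 0.11. The class II chain genes H2-Ob and H2-Oa fell by 0.72 ± 0.12 (664 against 1088) and 0.47 ± 0.10 (1652 against 2285). The class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 and the invariant chain gene Cd74 had differences of -0.09, -0.04, -0.10 and -0.08, none of which passed. The set did not shift (camera, adjusted p = 0.294). The number that fell was 2 without IRF4 KO replicate 1, 1 without IRF4 KO replicate 2 and 2 without WT replicate 2. Of 17 MHC class I presentation genes, 2 rose, the same number as adjusted over the list alone, and 15 did not pass. The peptide transporter gene Tap1 rose by 0.52 ± 0.10 and the transactivator gene Nlrc5 by 0.47 ± 0.10, with limma adjusted p values of 0.123 without IRF4 KO replicate 1 and 0.115 without IRF4 KO replicate 2 and 0.0591 without WT replicate 2 for Tap1 and of 0.125 without IRF4 KO replicate 1 and 0.175 without IRF4 KO replicate 2 and 0.0668 without WT replicate 1 and 0.0621 without WT replicate 2 for Nlrc5, whose probesets differ (adjusted p = 0.231 for their mean). The class I set was higher (camera, adjusted p = 0.0482), with adjusted p = 0.757 with an estimated correlation. Its camera adjusted p was 0.113 and 0.0876 without IRF4 KO replicates 1 and 2, 0.149 without WT replicate 2, 0.183 after quantile normalization, 0.0617 with each array's median subtracted, 0.233 with the stricter filter and 0.0771 with probesets averaged.

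Pattern-recognition receptors and migration genes moved in both directions. Of 21 pattern-recognition genes, 8 rose, 2 fell and 11 did not pass, and adjusted over the list alone 9 rose and 4 fell. The C-type lectin genes Clec4a3 and Clec4e rose by 1.75 ± 0.15 (683 against 206) and 1.03 ± 0.14 (62.8 against 30.7, below the filter level in WT cells, and 1.80-fold with WT set at that level) and the peptidoglycan sensor gene Nod1 by 0.93 ± 0.11, whereas the DNA sensor gene Aim2 fell by 0.82 ± 0.10. The set did not pass (camera, adjusted p = 0.116), but was higher with no brightness filter (0.00111) and without WT replicate 1 (0.0298). Without IRF4 KO replicates 1 and 2, 4 and 3 of its genes rose. Of 17 chemokine receptor and migration genes, 6 rose, 3 fell and 8 did not pass, and adjusted over the list alone 6 rose and 4 fell. Itgam, which encodes CD11b, rose by 0.92 ± 0.12 (604 against 319.7), and the prostaglandin E receptor gene Ptger4 fell by 1.13 ± 0.11 (276 against 604). This set did not shift (camera, adjusted p = 0.734). Its higher genes numbered 1 and 3 without IRF4 KO replicates 1 and 2 and 3 and 1 without WT replicates 1 and 2, and 1 of its genes fell without either IRF4 KO replicate.

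Markers of other spleen cells were measured on the same arrays, among them B cells and plasmacytoid dendritic cells, which the B220-negative gate should remove, and cDC1, which the CD24-negative gate should remove. Macrophage markers were higher in IRF4 KO cells: of 16 tested, 12 rose, 1 fell and 3 did not pass, with a median difference of 0.74, and adjusted over the list alone 12 rose and 2 fell. The complement genes C1qc, C1qb and C1qa rose by 1.26 ± 0.15 (385 against 162), 1.12 ± 0.16 and 1.01 ± 0.13, and the iron exporter gene Slc40a1 rose by 0.97 ± 0.10. The member that fell was Adgre1, which encodes F4/80, by 0.46 ± 0.10 (317 against 437), with a limma adjusted p of 0.128 without IRF4 KO replicate 1 and 0.183 without IRF4 KO replicate 2 and 0.0543 without WT replicate 1 and 0.0853 without WT replicate 2. The set was higher (camera, adjusted p = 9.85e-06), with adjusted p = 0.491 with an estimated correlation. It rose on the same arrays as the other 6 lists that were higher as sets, whose medians were 0.88 for mitosis, 0.63 for S-phase and 0.63 for interferon-stimulated genes, 0.38 for genes of the subset with low ESAM and of monocytes, and 0.19 and 0.19 for class I presentation and respiratory chain genes, and the lists that were lower as sets had medians of -0.25 for maturation and -0.19 for immediate-early genes. Of the macrophage markers, 7 rose without IRF4 KO replicate 1 and as many without IRF4 KO replicate 2, and none fell without any 1 of the 4 arrays.

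The remaining cell type lists did not shift as sets in camera. Of 17 cDC1 markers, 5 rose and 2 fell (7 and 4 when adjusted over the list alone; camera adjusted p = 0.282). They included Ifi205 and Irf8, which rose, and Wdfy4, a gene of cross-presentation, which fell by 0.86 ± 0.10 (856 against 1555), while Cd24a, which encodes the CD24 that the gate excludes, rose by 0.66 ± 0.11 (552 against 351; limma adjusted p 0.0874 without IRF4 KO replicate 1 and 0.0771 without IRF4 KO replicate 2) and the chemokine receptor gene Xcr1 was at 0.15 ± 0.18 and did not pass. Of 12 plasmacytoid dendritic cell markers, 5 rose and none fell, over all genes and adjusted over the list alone (camera, adjusted p = 0.19), with Atp1b1, a sodium pump subunit gene, at 1.34 ± 0.12 (84.2 against 33.2, below the filter level in WT cells, and 2.43-fold with WT set at that level) and Siglech at -0.05 ± 0.10, which did not pass. Of 11 B cell markers, 2 rose and 2 fell (4 and 3 adjusted over the list alone), among them Cd79b, a subunit of the B cell receptor, at 1.10 ± 0.14. The counts of higher and lower genes were 2 and 0 of 7 for neutrophil markers, with S100a8 at 0.96 ± 0.12 (66.0 against 33.8, and 1.90-fold with WT set at the filter level, below which it lay), 1 and 1 of 7 for natural killer cell markers, 2 and 0 of 8 for platelet markers, with Nrgn at 1.04 ± 0.12, and 1 and 0 of 11 for T cell markers, with Thy1 at 1.18 ± 0.14. They were 1 and 0 of 7 for erythroid markers, with Car2 at 1.80 ± 0.17, and 1 and 0 of 7 for plasma cell markers. Adjusted over the list alone, these 6 lists had 3 and 1, 2 and 1, 2 and 0, 1 and 0, 1 and 0, and 1 and 1 higher and lower genes. Camera adjusted p was 0.734 for B cell and neutrophil markers, 0.888 for natural killer and T cell markers, 0.902 for platelet and plasma cell markers and 0.954 for erythroid markers. The platelet list had a median of -0.14 and a mean of 0.14, the T cell list -0.07 and 0.05, and the erythroid list -0.05 and 0.21, and camera's direction was down for the plasma cell list against a median of 0.07. Without IRF4 KO replicate 1, the higher genes numbered 2 for cDC1, 1 for plasmacytoid and 1 for B cell markers, and without IRF4 KO replicate 2 they numbered 2, 2 and 2. Without WT replicate 1 they numbered 5, 3 and 2, and without WT replicate 2 they numbered 3, 3 and 1. The lower B cell markers numbered 0, 0, 1 and 0 and the lower cDC1 markers 1, 1, 2 and 1 without IRF4 KO replicates 1 and 2 and WT replicates 1 and 2. Of the smaller lists, neutrophil and platelet markers had 1 higher gene without either IRF4 KO replicate, neutrophil markers had 3 and natural killer cell markers 2 without WT replicate 1, natural killer cell markers had 0 without IRF4 KO replicate 1 or WT replicate 2, and plasma cell markers had 0 without either IRF4 KO replicate or WT replicate 1.

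Few genes of housekeeping and metabolic groups passed. None of 30 ribosomal protein genes passed in limma, and none reached an unadjusted p under 0.05, with a median difference of 0.02 (camera, adjusted p = 0.902). None of 26 mitochondrial respiratory chain genes passed in limma, over all genes or adjusted over the list alone, although 7 were higher at an unadjusted p under 0.05. As a set they were higher, with a median of 0.19 (camera, adjusted p = 0.00757), and adjusted p = 0.757 with an estimated correlation. Their camera adjusted p was 0.0984 without IRF4 KO replicate 1, 0.102 after quantile normalization and 0.0732 with the stricter brightness filter. None of 16 cholesterol synthesis genes (4 higher and 0 lower at an unadjusted p under 0.05) and none of 14 glycolysis genes (3 higher and 1 lower) passed in limma, and neither set shifted (camera, adjusted p = 0.294 and 0.529). Of 19 unfolded protein response genes, 1 rose and 1 fell, and of 10 type 2 and interleukin-4 responsive genes, 1 rose and 1 fell. Adjusted over the list alone, the counts were 1 and 1 and 2 and 1, and neither set shifted (camera, adjusted p = 0.734 and 0.902). Without IRF4 KO replicate 1 or 2 or WT replicate 2, no gene of these last lists passed in limma, and without WT replicate 1, 2 rose in each and none fell. Of the cholesterol synthesis genes 1 rose without either WT replicate, and of the glycolysis genes 1 fell without WT replicate 2.

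**Figure D2:**
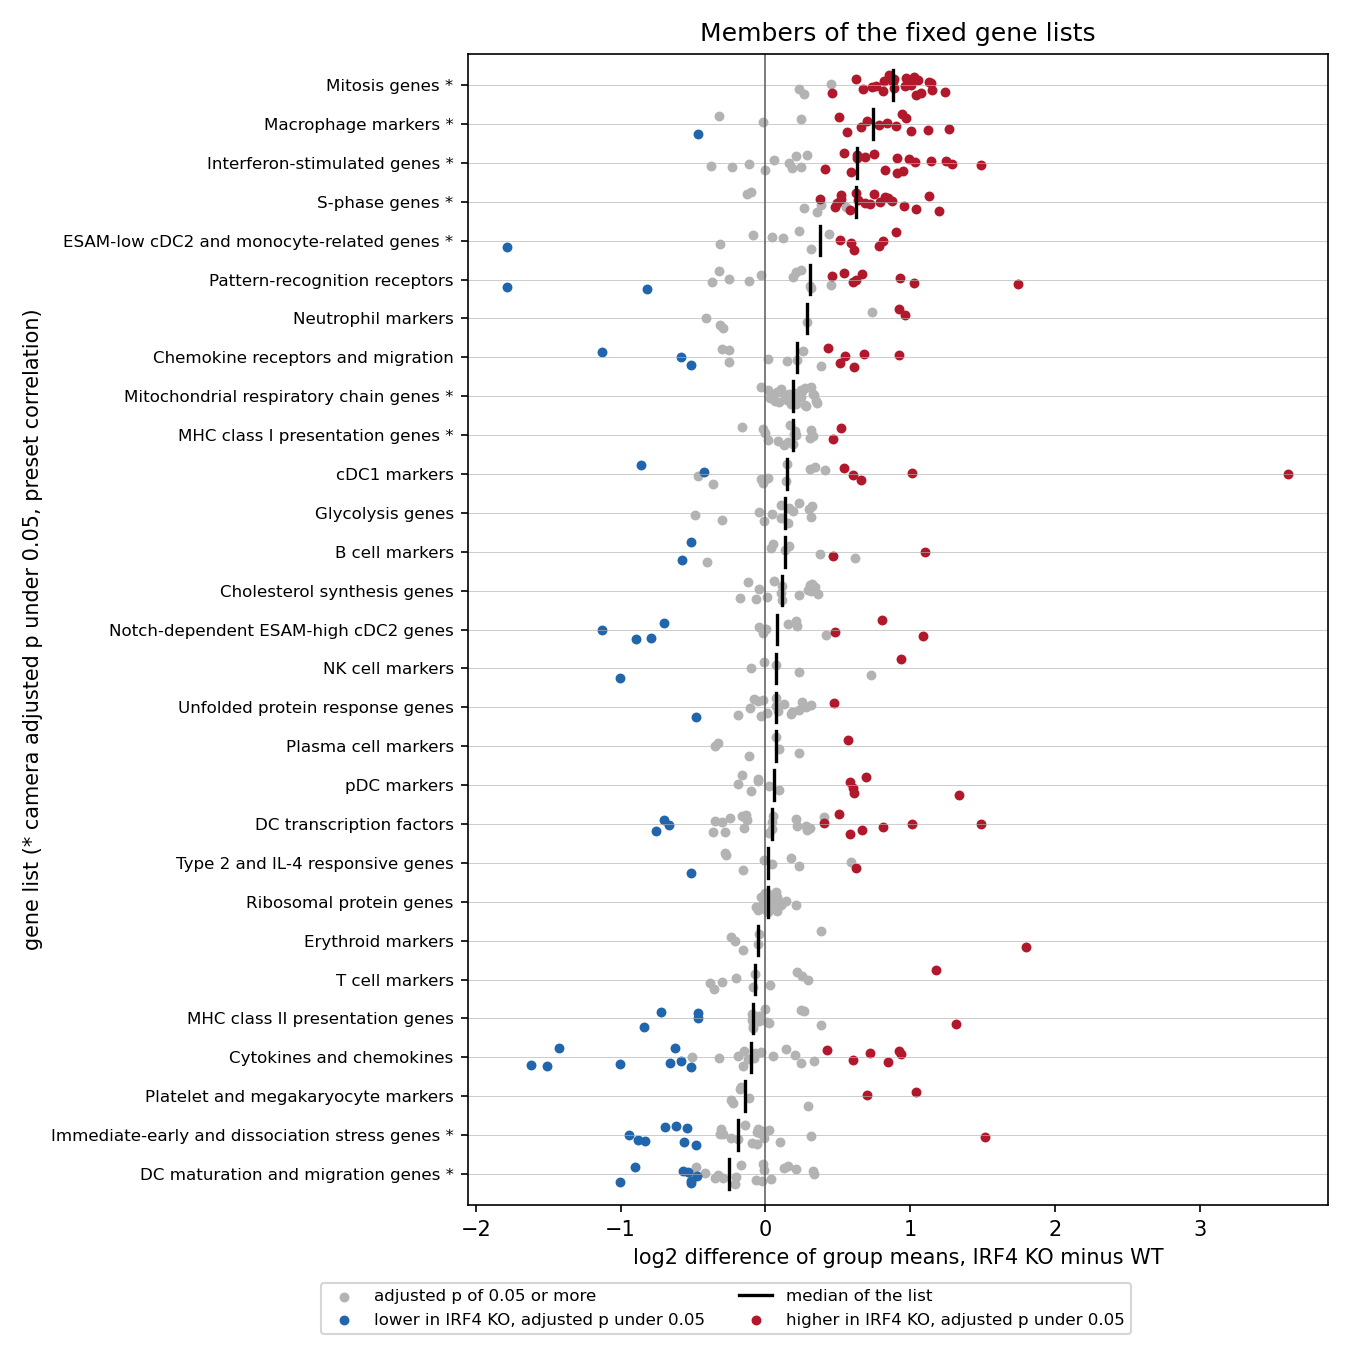
Log2 difference of the genotype means, IRF4 KO minus WT (horizontal axis), of each tested member of 29 gene lists (vertical axis, ordered by median), with 1 point per gene, red or blue where it was higher or lower at a limma adjusted p under 0.05 and grey otherwise, and a black bar at the median of the list. Asterisks mark the 9 lists past camera with its preset correlation; the medians run from 0.88 for mitosis genes to -0.25 for maturation genes.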

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

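The split of these probesets into 2 separate fits was chosen after a fit of both kinds together had been seen. Signal was present in probesets that the comparison of genes does not use. Of 3666 probesets above the filter level that the annotation does not list, 3 were higher and 1 was lower in IRF4 KO cells (limma, adjusted p under 0.05 within this kind). Of 886 probesets with several gene symbols, 41 were higher and 4 were lower. Fitted together, the first kind had 4 higher and 1 lower and the second 10 higher and 0 lower, a count of 10 against 45 for the second kind; the cause was not tested. No explanation was weighed for these values.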

How the results depend on the processing

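The alternatives for genes and lists were planned, whereas the other probesets were fitted together first and the separate fits were chosen after that result was seen. No called gene or list that the naming rule or the fixed lists hold turned its direction under any alternative run. Irf4 had differences from -3.37 to -3.23, with limma adjusted p between 4.96e-09 and 0.00056, and the 24 genes with the largest differences passed in all 262 values, with a highest adjusted p of 0.0463. The counts of called, higher and lower genes were 809, 557 and 252 with no brightness filter, for which the cause was not tested, and 179, 123 and 56 with an absolute log2 difference of at least 1. With the adjusted p threshold at 0.10, 2353 genes were called, 1578 higher and 775 lower. The counts were 1304, 757 and 547 after quantile normalization, 1777, 1417 and 360 with each array's median subtracted, which shifted the median of all tested genes from 0.02 to 0.08, 1600, 1173 and 427 with the stricter filter, 1496, 1053 and 443 with probesets averaged, and 2115, 1527 and 588 with a trended, robust variance. With 1 array left out they ranged from 366 to 1271, from 235 to 909 and from 131 to 362. Of 1485 called genes, 361 were called without IRF4 KO replicate 1, 483 without IRF4 KO replicate 2, 987 without WT replicate 1 and 900 without WT replicate 2, all in the same direction, and fewer arrays were then fitted. With the replicate number as a block 1698 genes were called (1174 higher and 524 lower) and 9 lists passed. The labels share only a number, so the design fixed beforehand assumed no pairing. The deviations of the first arrays from their group means had a correlation of 0.148 over 12364 genes in 2 pairs. This value did not decide that choice, and a shared effect of the replicate number stays open. Of the lists, 0 passed with an estimated correlation (0 higher and 0 lower, 2 at an unadjusted p under 0.05), and 3 by fry (3 higher and 0 lower); for both the cause was not tested. With 1 array left out 6 to 10 lists passed, 4 to 8 higher and 2 lower, and the stricter filter left 4 higher and 3 lower, for which the cause was not tested. Of 9 lists that passed camera, 2 were lost after quantile normalization and 2 with each array's median subtracted. Of 93 called named genes, 16 were lost with no filter, 6 after quantile normalization, 2 with probesets averaged, and 24, 22, 11 and 15 without IRF4 KO replicates 1 and 2 and WT replicates 1 and 2. Signal over background was not measured, since the values hold no detection calls: 88 rose and 92 fell among the dimmest 3091 tested genes, against 362 and 168 among the brightest 3091.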

Other observations

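The heat-shock list, the scan of neighbouring genes, the histone test, the Ly6C-low monocyte list with its test and the red pulp macrophage test were chosen after the results were seen, as were the genes named here that the naming rule did not pick. Of 18 tested genes of heat-shock chaperones and their partners, 8 rose and none fell in IRF4 KO cells, with a median log2 difference of 0.45. The list holds Hspa1a and Hsph1, whose rise was seen before it was written, so it is no independent evidence of its direction. Hsph1 rose by 1.58 ± 0.17 (SE; 795 against 269), Hspd1, a mitochondrial chaperonin gene, by 0.74 ± 0.11, and Hsp90aa1 and Dnajb1 by 0.56 ± 0.11 and 0.57 ± 0.10, while Hspb1 was at 0.04 ± 0.10 and did not pass. The list was higher as a set (limma's camera, unadjusted p = 3.02e-07), with unadjusted p = 0.0512 with an estimated correlation. Its higher genes numbered 3 without IRF4 KO replicate 1, 2 without IRF4 KO replicate 2, 6 without WT replicate 2, 4 with no brightness filter and 6 after quantile normalization. Hsp90aa1 and Dnajb1 did not pass with IRF4 KO replicate 1 or 2 left out, and Hspd1 did not pass without IRF4 KO replicate 2.

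Several of the genes with differences of at least 1 lay side by side in the genome. Among windows of 7 adjacent tested genes, the highest count of such genes was 5, in the Ifi200 cluster, where Ifi213 and Ifi207 rose by 1.02 ± 0.14 and 1.02 ± 0.11 beside Ifi205, Ifi206 and Ifi203. The next was 4, where Zcwpw1 rose by 1.33 ± 0.13 beside Pilra, Pilrb1 and Pilrb2. None of 1000 random orders of the genes reached 5 (permutation, highest count over windows; the 95th percentile was 3). The Ifi200 and Pilr genes are similar in sequence, so their probesets may share signal, which no test here separated; all of these 9 genes stayed past a limma adjusted p of 0.05 without any 1 array, with 0.0463 for Ifi206 without IRF4 KO replicate 1 as the highest value. The purinergic receptor genes P2ry13 and P2ry14 and their neighbour Gpr171 rose by 1.47 ± 0.25, 1.11 ± 0.15 and 1.09 ± 0.12, and P2ry13 did not pass without IRF4 KO replicate 1. Their count of 3 only equals the 95th percentile of the random orders, so this cluster does not stand out from them. Other windows with 3 such genes held C1qa, C1qb and C1qc, or Oas1a, Oas2 and Oas3, or Ccl3, Ccl4 and Ccl5. Another held Mir680-1, Klri1 and Klri2.

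Genes that neighbour Irf4 were called more often than other genes, 25 of 100 against 1458 of 12254. The odds ratio was 2.47 (95% interval above 1 and up to 3.94, Fisher exact p = 0.000281, which takes genes as independent although changed genes lay in clusters). Overlapping windows of the same number of tested genes as Irf4 and these neighbours were counted for genes with differences of at least 1. The window of Irf4 held 8, Irf4 itself among them. At least as many were held by 116 of 10352 windows, that of Irf4 included, and the highest count was 11. These windows overlap, so 116 is not a number of separate regions. A candidate explanation is DNA of another strain carried along with the deletion, and the excess met the criterion set for it in advance, but 17 of the 100 are histone genes, of which 9 rose (of all 22 tested histone genes 10 rose, and 6 without IRF4 KO replicate 1). Without histone genes the odds ratio was 1.77 (0.954 to 3.10, Fisher exact p = 0.0588), an interval that holds both 1 and the first ratio. For called genes with differences of at least 1, the odds ratio was 5.32 with all neighbours (7 of 100). Without histone genes that ratio was 1.74 (2 of 83, 95% interval 0.206 to 6.60, Fisher exact p = 0.325). Passenger DNA and histone genes of dividing cells therefore cannot be told apart. The stricter reading that leaves out histone genes was set after the result. With all neighbours the ratio was 3.30 without IRF4 KO replicate 1 (9 of 100 called), 4.23 without IRF4 KO replicate 2 (15 of 100) and 1.63 with the stricter brightness filter (Fisher exact p = 0.0752), and without histone genes it ranged over the 11 alternatives from 1.12 with the stricter filter (Fisher exact p = 0.744) to 2.55 without IRF4 KO replicate 2 (0.0188), with 1.25 without IRF4 KO replicate 1 (0.736) and p under 0.05 in 4 of the 11. Close to Irf4, Serpinb6b fell by 1.62 ± 0.13, Serpinb9 fell by 1.41 ± 0.13 and Dusp22 rose by 0.87 ± 0.12 (limma adjusted p = 0.0526 without IRF4 KO replicate 1), whereas Exoc2 was at 0.10 ± 0.10 and did not pass; an effect of IRF4 loss on these genes was not tested apart from their position.

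More genes rose than fell, 1045 against 440, and the balance changed with brightness: 88 rose and 92 fell among the dimmest 3091 tested genes, and 362 and 168 among the brightest 3091. The deposited distributions were wider for IRF4 KO arrays, which could tilt calls in this way. After quantile normalization 75.7% of the called genes were called in the same direction, between the limits of 50% and 80% set in advance for and against this explanation, and 757 genes rose against 547, 58.1% of the calls, whereas subtracting each array's median moved that share the other way, from 70.4% to 79.7%. A real excess of higher genes in IRF4 KO cells stays open beside a difference in distribution, since each was present on both arrays of the genotype. The number of called genes ranged from 366 without IRF4 KO replicate 1 to 1271 without WT replicate 1.

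Macrophage markers rose together with Treml4, Ace, Adgre4 and Clec4a3, genes of monocytes with low Ly6C, which rose by 1.64 ± 0.13, 1.79 ± 0.12, 1.42 ± 0.10 and 1.75 ± 0.15. More such monocytes in the sort may be the source, although the gate asked for MHC class II, which many of them carry little of. The list of these monocytes without those 4 genes had a median of 0.28 (bootstrap 95% interval 0.14 to 0.59). This was below the limit of 0.5 but not by more than its spread. Camera gave this list unadjusted p = 0.00156, and unadjusted p = 0.313 with an estimated correlation. Of its 15 tested genes 7 rose, including Csf1r and Cx3cr1, which the fixed list of the subset with low ESAM and of monocytes also holds, and 0, 3 and 3 did without IRF4 KO replicate 1, IRF4 KO replicate 2 and WT replicate 2; its brightest genes were Nr4a1 (2955 against 3657, not called) and Csf1r (884 against 589). Red pulp macrophages, which carry little CD11c and MHC class II, so that the gate would remove many of them, are another candidate source: all 9 tested genes of their list rose, with a median of 0.70 (0.51 to 0.94; camera, unadjusted p = 6.58e-08, and unadjusted p = 0.0739 with an estimated correlation), among them Hmox1 (956 against 533), and 3 and 4 rose without IRF4 KO replicates 1 and 2, but 8 of the 9 are among the macrophage markers that showed the pattern, so this test decides nothing. Adgre1, a macrophage gene, fell by 0.46 ± 0.10, with a limma adjusted p of 0.128 without IRF4 KO replicate 1 and 0.183 without IRF4 KO replicate 2 and 0.0543 without WT replicate 1 and 0.0853 without WT replicate 2; other cells in the sort and a change within the dendritic cells stay open.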
